A study of Homo sapiens with 4 samples.

How the data were processed

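RNA of parental MDA-MB-231 cells and of the SUV420H2-expressing clone was measured on 4 one-colour arrays, 2 a group. Both kinds of cells were grown in medium with 10% serum, per the labels' protocols. RNA was isolated with a column kit, amplified as amino allyl aRNA, coupled to Cy5 and hybridised as the array's maker prescribes, per the labels' protocols. The arrays were read at 635 nm on a human chip of the 25k type, per the file headers. The scanner files as deposited give the intensity of each spot and of the ring around it as median pixel brightness, with no normalization or background subtraction recorded in the file headers. The photomultiplier gain was 38 on the array of parental replicate 2 and 39 on the others, per the file headers. The software and the authors' statistical methods are not given in the sources used here.

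The value table deposited by the authors holds linear processed intensities. Set against the scanner files, each column was proportional to 1 file's spot medians minus the blank level, with a median of 25 and a lowest value of 1.20, so the table is neither on a log scale nor centred per probe. For table values over 20, its scale and direction are thus settled by the scanner values. Lower table values were not compared in this way. Its rows carry the probe IDs of those files. The deviations from proportionality, at most 0.0513 in SD on the log2 scale, were computed over a mean of 10616 probes a column with a table value over 20.

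Probes were grouped by the samples named in the labels. Before the data were examined, the main comparison was fixed as one on the scanner intensities, each file taken with the sample it is attached to, and the value table was fixed as an alternative. Since these records disagree about which array belongs to which sample, both comparisons are reported in full. Groups were never assigned from expression levels. The match of table columns to files used only the proportionality of their values.

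For the scanner intensities, the background was corrected by normexp with an offset of 50 on the spot medians of all spots, control spots were then left out, and the arrays were quantile normalized and put on the log2 scale with limma 3.58.1 in R 4.3.3. The ring around a spot was not used as local background, because on spots brighter than 500 it read a median of 32.7% to 48.7% of the spot itself. It was tried as an alternative chosen after seeing the data. A probe was above background if its spot exceeded the mean of the array's 2680 blank spots by 2 SD, and was tested if this held on both arrays of at least 1 group. The 316 other control spots and 1 spot flagged by the scanner were left out. Every probe had 1 spot. The value table was tested as log2 of its values, with no pseudocount, over probes with 4 values. Groups were compared with lmFit and eBayes without a block, two-sided, with Benjamini-Hochberg adjustment over the probes tested. A fold change is on the scale of these values, and the offset of 50 makes it smaller for dim probes. The fit was tested on simulated data in which 200 probes were changed by known amounts and noise was independent between arrays.

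The alternatives fixed beforehand were other background corrections, 3 other normalizations, the value table, other filters on dim probes, the replicate number as a block, another variance model, an unmoderated test and leaving out each array. Those on the value table's own comparison, the crossed pairing, the local background and the scanner intensities grouped by the value table were added after seeing the data. The same-numbered samples carry only a number in the labels. Scan day coincided with the replicate number in the files' record, so its block is the replicate block there.

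Probe IDs are those of the chip's design. Of 24460, 1 matched a gene, KRT8, through an accession in a RefSeq gene table of the assembly GRCh38.p14, and 0 equalled any other name there. The 28 gene lists fixed beforehand, the SUV420H2 check and the averaging of a gene's probes were therefore not run. The rule for naming items was, among calls with no overlap between groups, those with the largest rise and fall. It was limited to 2 IDs a direction because the IDs carry no gene name. For a main comparison without calls, the rule fixed beforehand was another. It was to give the largest changes without overlap between groups as values, not as rises or falls. This was not followed. The rule for calls was applied to the value table instead, so the probes named there depart from the plan. KRT8 was named after its values were seen, as the only gene that could be. No column of per-sample values was left unused.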

Results

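Gene expression was measured in MDA-MB-231 cells, an invasive human breast cancer line, and in a clone of the same line made to express SUV420H2 stably. SUV420H2 (now KMT5C) is a histone methyltransferase of heterochromatin. The design asks which transcripts differ between the clone, named H2#9, and the parental cells it came from. Total RNA was amplified, labelled with Cy5 and hybridised to 1-colour arrays of 24460 probes, with 2 arrays for the parental cells and 2 for the clone. The labels do not say whether the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. One clone was compared with its parent, so a difference between them cannot be assigned to SUV420H2 rather than to the clone. The number of arrays limits the precision of every value below.

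By the samples the scanner files are attached to, the median spot brightness of the probes was 67 and 63 on the parental arrays and 69 and 66 on the clone arrays. Blank spots averaged between 47.2 and 47.9. Between 14666 and 16854 probes lay above background on an array, which is 60.0% to 68.9% of all probes. The arrays of the first scan day had fewer, 14666 and 16004, than those of the second, 16854 and 16757. Blank spots varied more on the first day, with SDs of 4.29 and 3.59 against 2.09 and 2.33, which raised the threshold there. The brightest spot read 58237. A second set of values was deposited as 1 table of processed intensities, in which each sample's column has a median of 25 and some cells are empty. All 4 of its columns held a value for 18384 probes and none did for 3206.

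The 2 deposited records put the arrays in different samples. Each column of the authors' value table followed 1 scanner file closely, with an SD of the log2 difference between 0.0454 and 0.0513. Against the other 3 scanner files the SD was between 0.223 and 0.414. Among probes with a table value over 20, 97.7% to 98.7% lay within 10% of proportionality for the matching file and at most 53.6% for any other. For 3 of the 4 columns the matching file was attached to another sample. The table's first parental column matched the file of parental replicate 2, its second parental column the file of clone replicate 1, and its first clone column the file of parental replicate 1. Clone replicate 2 was the same array in both records. The group therefore differed for 2 of the 4 arrays, and the comparison of clone with parental cells was made under each record.

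**Figure D1:**
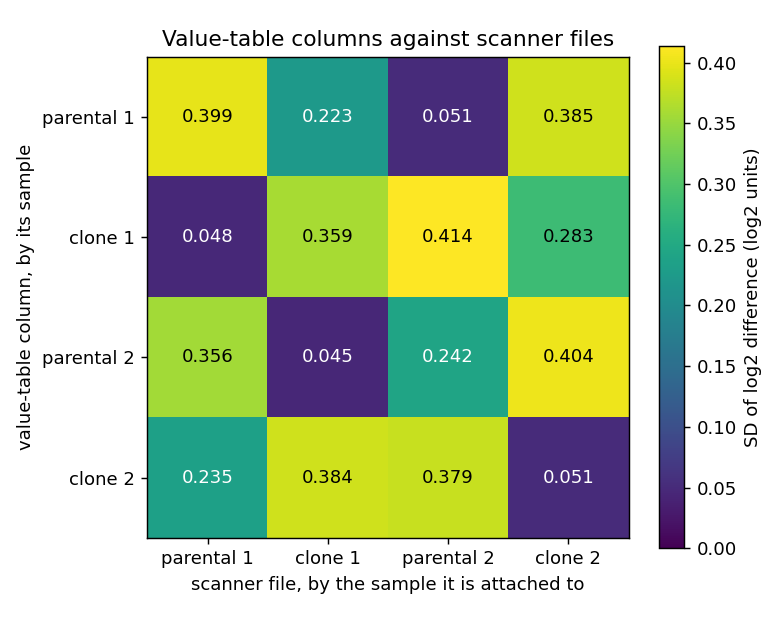
Each cell gives the SD (log2 units) of the difference between a column of the authors' value table (rows, by sample) and a background-subtracted scanner file (columns, by the sample it is attached to). The lowest SD of each row, 0.0454 to 0.0513, lies on the diagonal only for clone replicate 2.

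By the record of the scanner files, no probe passed the test between the clone and the parental cells. Of 15746 probes tested, 0 passed an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), the lowest adjusted p was 1, and 60 had an unadjusted p under 0.05, which is 0.381% of those tested. An unmoderated test called 0 as well, with 370 at an unadjusted p under 0.05. Both counts lie below the share of 0.05 that independently varying arrays would give without any difference. They are therefore no evidence that the groups are alike. Data were simulated with 15746 probes and variances from this comparison's fit, with noise independent between arrays. The same fit recovered 62 of 100 probes changed by 1 on the log2 scale and 89 of 100 changed by 2. The measured arrays did not vary independently, as the pairs below show, so this does not give the power behind the count of 0. Arrays of the same group were less alike than arrays of different groups. The SD of log2 differences over the 14481 probes above background on all 4 arrays was 0.247 between the parental arrays and 0.235 between the clone arrays. It was 0.141 between clone replicate 1 and parental replicate 2, 0.159 between parental replicate 1 and clone replicate 2, and 0.220 and 0.226 for the other 2 pairs of a parental and a clone array. The 2 closest pairs were scanned on different days.

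**Figure D2:**
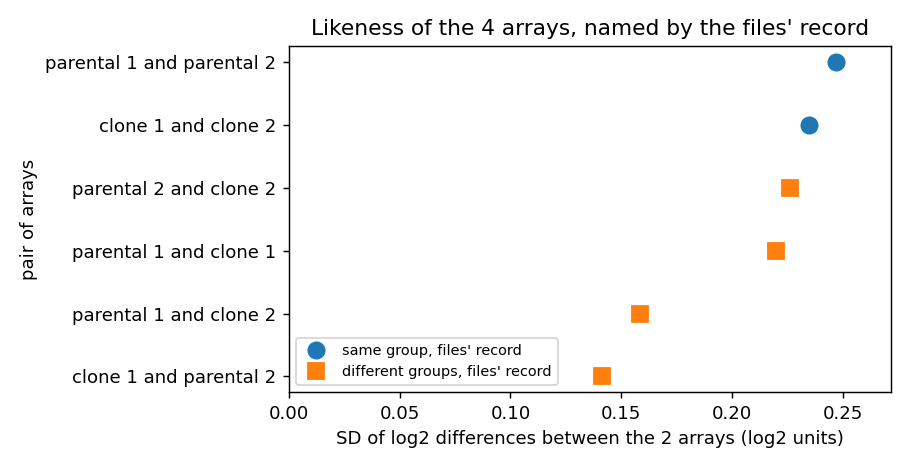
Each point is a pair of arrays, named by the samples their scanner files are attached to, placed by the SD of their log2 differences (log2 units) over 14481 probes. The lowest SDs, 0.141 and 0.159, belong to pairs that join a parental with a clone array.

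By the authors' value table, 349 of 18384 probes differed between the clone and the parental cells at an adjusted p of 0.05 in limma. Of these, 144 were higher and 205 lower in the clone, and 2944 probes, 16.0% of those tested, had an unadjusted p under 0.05. A change of at least 1 on the log2 scale was seen for 267 of the 349, with 111 higher and 156 lower. The median change of the called probes was 1.19 on the log2 scale, whatever its direction, and the range ran from -4.21 to 3.87. Over all probes tested the median log2 fold change was -0.0900, and quantile normalization, which brings it to -0.000477, turned the balance to 252 higher and 208 lower. Without any 1 of the columns 0 probes passed in limma, with 1338 to 2613 at an unadjusted p under 0.05. This leaves 1 column in a group and assumes that it varies like the other group, so the lost calls do not show dependence on any column. Data were simulated in the same way for this comparison, with 18384 probes and noise independent between arrays. In these, 38 of 100 probes changed by 1 and 98 of 100 changed by 2 were recovered. The simulated variances came from the fit itself and did not depend on intensity. In the measured columns, the deviations of same-numbered columns correlated at -0.27. The simulation therefore does not give the power behind the 349 calls.

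Each scan day held 1 parental and 1 clone column of the table. All 349 called probes had the same direction on both days, as their selection from these same columns favours, with a median change of 1.20 on the first day and 1.23 on the second. With scan day as a block, 614 probes passed, 219 higher and 395 lower. Tested on the scanner intensities with the groups of the table, 676 probes passed, 324 higher and 352 lower, but only 42 by at least 1 on the log2 scale. A pseudocount of 10 on the table's values, chosen after seeing the data, gave 524 calls, 97 of them by at least 1. With the empty cells filled at the lowest value, also chosen after seeing the data, 2 of 24460 probes passed, 0 higher and 2 lower. Among the 15837 probes tested both ways, 318 and 667 were called. Both ways called 196 probes, on the same 4 arrays.

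**Figure D3:**
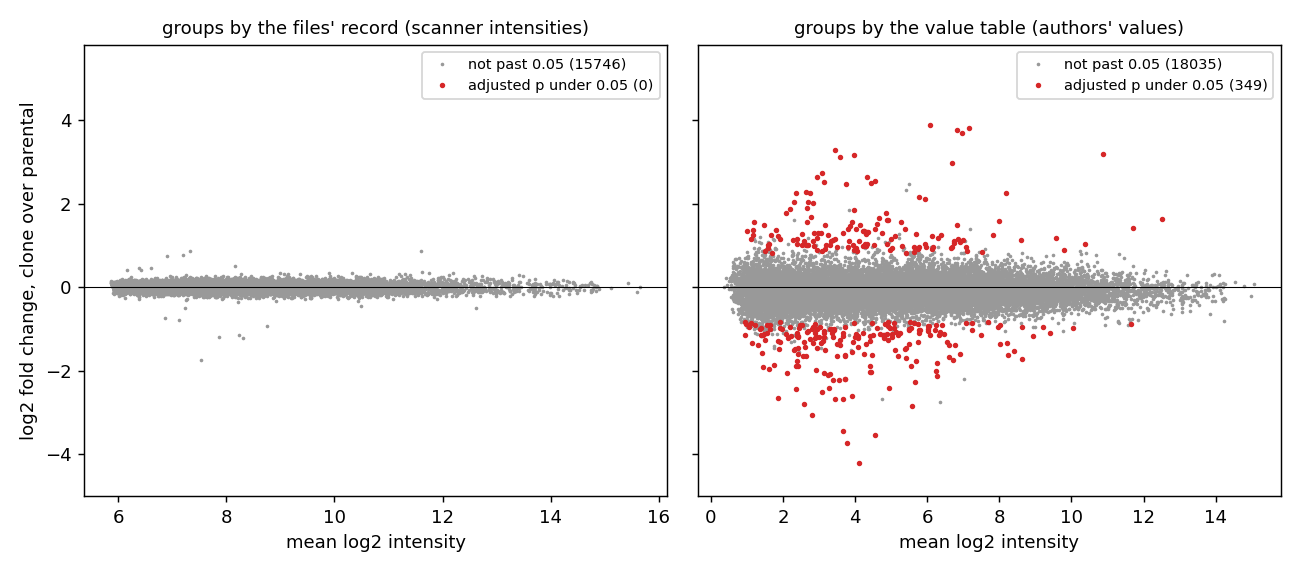
Each point is a probe, with its mean log2 intensity on the x axis and its log2 fold change, clone over parental, on the y axis. Red points pass an adjusted p of 0.05, which holds for 0 of 15746 probes by the record of the scanner files (left, values with an offset of 50 that shrinks the folds of dim probes) and for 349 of 18384 by the authors' value table (right).

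The largest rise in the clone by the value table was that of probe opHsV0400000243, from an intensity of 17.7 ± 0.0707 in the parental cells to 259 ± 7.64 in the clone (SD, n = 2), a log2 fold change of 3.87 with an SE of 0.162 and a limma adjusted p of 4.53e-05. Probe opHsV0400000321 followed, with 38.6 ± 3.25 in the parental cells and 535 ± 3.96 in the clone (log2 fold change 3.80). The most negative fitted change was that of probe H200006199, from 74.6 ± 6.01 to 4.05 ± 0.636 (log2 fold change -4.21, SE 0.184, adjusted p 4.53e-05). Probe CHsGV10003603 fell from 50.5 ± 8.27 to 3.85 ± 0.778 (log2 fold change -3.72). Both falling probes lay above background on only 1 of the 2 clone arrays, so the size and order of their falls are uncertain. On scanner intensities in the same groups they were -1.49 and -1.10, and with a pseudocount of 10 they were -2.59 and -2.12. The rises were 2.52 and 3.02 on scanner intensities and 3.28 and 3.49 with a pseudocount of 10, so their order turned in both. By the record of the scanner files the same 4 probes had log2 fold changes of -0.105 (SE 1.24), -0.0915 (SE 1.48), 0.0223 (SE 0.731) and -0.0471 (SE 0.545), in the order named, each with an adjusted p of 1. Each group of that record holds 1 array from each group of the value table. Small fold changes with large SEs therefore follow from how these probes were picked, and are no separate result. The files do not pair these IDs with genes.

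KRT8, keratin 8 of simple epithelia, was the only gene that could be named, through the RefSeq accession in its probe's ID. Its log2 fold change, clone over parental, was 0.19 (SE 0.198, limma adjusted p 0.698) by the value table, from 223 ± 35.3 in the clone and 196 ± 32.2 in the parental cells (SD, n = 2). By the record of the scanner files it was -0.0366 (SE 0.139, adjusted p 1), with log2 intensities of 8.51 ± 0.247 and 8.55 ± 0.0508. Neither passed the test. KRT8 has many processed pseudogenes, with which a probe can share sequence. The level of SUV420H2 itself, which would check the labels, and those of SUV420H1, SETD8 and the tensins are not reported here, because 0 probe IDs carry those names.

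Some probes had a value in the table in only 1 group. A value in both clone columns and neither parental column was found for 93 probes, and the opposite for 229. Splitting the same columns by scan day gave 249 and 88, so that presence and absence parted the scan days about as often as the groups. Splitting by replicate number gave 77 and 108.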

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

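By the record of the scanner files, the count of changed probes was 0 under every alternative that kept that record, and also 0 at a change of at least 1 on the log2 scale. These were no background correction, normexp with offset 0 or with local background, median, 75th percentile and cyclic loess scaling, no filter or a filter on all 4 arrays, the trended robust prior, the unmoderated test, and leaving out each array. The replicate block also gave 0, with 13 probes at an unadjusted p under 0.05. The deviations of same-numbered arrays correlated at -0.469, as with crossed numbers or with files exchanged between the groups, which this does not separate, and the crossed pairing as a block gave 0. The record decided the count: the value table gave 349 (267 at least 1), and scanner intensities in the groups of that table gave 676 (42). KRT8 by the files' record changed sign under 5 alternatives, to 0.0920 with median scaling, 0.192 in the value table, 0.319 with local background, 0.211 with the table's groups and scanner intensities; leaving out arrays gave -0.214 to 0.141. Its lowest adjusted p, 0.234 in limma, came with the table's groups and scanner intensities, which do not keep the files' record. Nor do the sign changes in the value table and with the table's groups.

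By the value table, where every alternative was added after seeing the data, 349 probes (144 higher, 205 lower, 267 at least 1) became 524 (198, 326, 97) with a pseudocount of 10, 460 (252, 208, 272) with quantile normalization, 831 (285, 546, 174) over probes above background on all 4 arrays, 614 (219, 395, 290) with scan day as a block, 1231 (396, 835, 296) with the trended robust prior, and 676 (324, 352, 42) on scanner intensities. With empty cells at the lowest value, 2 passed (0 higher, 2 lower, 2 at least 1), over 24460 probes. Leaving out any 1 column gave 0 in each count (range 0 to 0), with the remaining column of a group assumed to vary like the other group and lowest adjusted p of 0.188 to 0.205. The replicate block gave 487 (189, 298, 330); same-numbered columns deviated with a correlation of -0.27, and the crossed pairing is the scan day block. The 4 named probes kept their direction under all of these settings that tested them, and each lost its call in 5, the 4 omissions and the filled cells. In the omissions, which leave 1 residual degree of freedom, their log2 fold changes were 3.84 to 3.90 (opHsV0400000243), 3.71 to 3.88 (opHsV0400000321), -4.37 to -4.05 (H200006199) and -3.92 to -3.51 (CHsGV10003603). Filled cells cannot move the fold of a probe with 4 values; the adjusted p rose to between 0.055 and 0.128. Apart from the settings named, the cause was not tested. With 2 arrays a group and 31.1% to 40.0% of probes not above background on an array, changes of dim probes are the least certain.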

Other observations

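The tests of likeness, scan day, brightness and other splits were chosen after the results were seen; the counts of 0 and 349 were planned.

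A biologist reusing these arrays would first need to settle which array is which. For 3 of the 4 samples the scanner file and the value-table column came from different arrays. By the files' record, the SD of log2 differences within groups was 1.29 times that between groups, and by the value table's record 0.646 times. The first value is consistent with scanner files attached to the wrong samples, and gives a candidate explanation for a count of 0 changed probes beside 349. That value-table columns were given to the wrong samples stays open: likeness shows which arrays resemble each other, not which are the clone, and 0 probes can be named SUV420H2, whose level would decide. No biological explanation of the disagreement was tested.

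Across the groups of the files' record, the arrays parted 2 against 2, with the files of parental replicate 1 and clone replicate 2 on one side. Of the 3 splits of the 4 arrays into 2 and 2, too few for a share under 0.05, this one called 676 probes on the scanner intensities, the files' record 0 and scan day 0 in limma, with 3377, 60 and 643 probes at an unadjusted p under 0.05. In these fits without a block, the parting lies in the residual spread of the other splits, so their low counts exclude no effect of their own. The crossed pairing of the files' record is this same parting. As a block it took the parting out of the residual, and the files' record still gave 0 calls, with 125 probes at an unadjusted p under 0.05 in limma. Its residual is then the difference between scan days, with 1 degree of freedom, so this 0 does not show that the groups are alike. Scan day is argued against as the source of this parting: of the 2 pairs of arrays most alike, which form the sides, 0 were scanned on the same day, so each side holds 1 array of each day. This is the third test of scan day tried; the count of calls above and a ratio of SDs between pairs (0.220 over 0.159) were dropped as deciding nothing, since the design or the choice of sides fixed them. Scan day still parted presence in the value table, as reported. Overall brightness of the arrays is argued against too. In the 75th percentile of spot brightness before normalization, the arrays of one side (175 and 174) lay between those of the other (196 and 157). The lowest of the latter minus the highest of the former was -18. The parting was measured after quantile normalization, which evens out overall brightness, and effects that depend on intensity were not tested. Expression that differs between the clone and the parental cells stays an open explanation, since this split is also that of the value table's groups, as do differences between cultures or RNA preparations, which the labels do not describe.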
